A study of Homo sapiens with 9 samples.

How the data were processed

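RNA was sequenced in 9 libraries of SKOV3, an established human ovarian cancer cell line: 3 libraries labelled control, 3 labelled Carbo and 3 labelled Carbo+COM33. Carbo is read as carboplatin, a platinum drug that crosslinks DNA, from the title of the series. COM33 is known here only by its code name. The labels give neither doses nor times of treatment, and there is no group with COM33 alone. Per the labels, messenger RNA was selected with poly-T beads, libraries were made with a NEBNext Ultra RNA kit, and paired-end reads were generated on an Illumina sequencer. The labels do not say whether the replicate numbers mark separate cultures, days or aliquots, so the p-values below measure only the spread between these samples, which may be technical.

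The authors deposited a table with read counts per gene, in whole numbers, for each of the 9 libraries, and a second block of deposited FPKM values (fragments per kilobase of transcript, scaled to library size). Per the submitters' processing notes, HISAT2, HTSeq 0.11.2 and DESeq2 1.26.0 were used on the human genome build GRCh38; the notes do not state the settings, the strand setting of the counting included. All 32378 gene identifiers and names of the table matched GENCODE release 29, from which chromosome, start, end and strand were taken. The deposited FPKM values equalled the count divided by gene length and by the library's total count, with a largest difference of 8.2e-12. For 32283 genes the length used was that of the union of exons, within 0.5 bp. Every gene in the table had a count in some library, so genes with no counts had been left out before deposition. The counts were used for all tests, and FPKM only in alternatives.

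Total counts per library were 14484867, 14869356 and 14525682 for control 1 to 3, 14791959, 15533668 and 14360199 for Carbo 1 to 3, and 13851760, 14501036 and 14589180 for Carbo+COM33 1 to 3. These totals limit the precision of low counts; the errors given in the text are standard deviations (SD) between libraries or standard errors (SE) of the fit.

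Genes were kept by the filterByExpr function of edgeR 4.0.16 with the 3 groups, which left 16450 genes. Library sizes were scaled by TMM, and the normalization factors ran from 0.982 to 1.01. A quasi-likelihood negative binomial model was fitted to all 9 libraries with a coefficient per group (6 residual degrees of freedom, common dispersion 0.0133). The 3 comparisons were Carbo vs control, Carbo+COM33 vs Carbo and Carbo+COM33 vs control. Throughout, an adjusted p is edgeR's quasi-likelihood p after Benjamini-Hochberg adjustment over the 16450 genes, and a gene is called when it lies under 0.05. The SE of a log2 fold change is its size divided by the square root of its F statistic. Levels are in CPM, counts relative to the TMM-scaled library size, as mean ± SD over n = 3 libraries. R 4.3.3, limma 3.58.1 and DESeq2 1.42.0 were used, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

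Replicate numbers may pair libraries. Among 6607 genes with a mean log2 CPM over 5, the deviations of same-numbered control and Carbo libraries from their group means correlated across genes at 0.825, 0.565 and 0.748 for replicates 1, 2 and 3. Genes are not independent replicates, so these values carry no p. Because each of these was over 0.1, Carbo vs control was also tested with the replicate number as a block in the 6 control and Carbo libraries alone (2 residual degrees of freedom). This paired fit stands beside the unpaired values.

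A set of 33 gene lists was fixed before the data were examined, as were the comparisons, the tests, the alternatives and the rule for named genes. Excepted are the alternatives given below as later additions, and the parts of the naming rule that use the paired fit. The lists cover EMT (epithelial-mesenchymal transition) transcription factors, mesenchymal genes, epithelial genes, ERK transcriptional output, MAPK cascade components, AP-1 and immediate early genes, p53 targets, DNA repair, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, apoptosis regulators, NF-kB and inflammatory cytokines, interferon-stimulated genes, ATF4 and the unfolded protein response, NRF2 antioxidant genes, heat shock proteins, cholesterol synthesis, hypoxia and glycolysis, TGF-beta targets, WNT targets, YAP and TEAD targets, integrins and focal adhesion, platinum transport and resistance, metallothioneins, ribosomal proteins, mitochondrially encoded genes, nuclear genes of oxidative phosphorylation, nuclear-retained long RNAs, senescence and secretory genes, and markers of other cell types (blood and immune cells; endothelium, nerve, liver and muscle; mesothelium and fallopian tube). Some genes stand in more than 1 list. Lists with at least 5 tested genes were tested with camera of limma on log2 CPM (prior count 2) with the preset correlation of 0.01 between genes, and p was adjusted over the 32 lists tested. Camera compares a list with all other genes. Each test was repeated with the correlation estimated from these libraries and with fry, which asks whether a list's genes move on balance in one direction and compares them with no other genes. Counts "adjusted over the list alone" use the Benjamini-Hochberg adjustment within a list.

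The genes named are, for each comparison, the 12 with the largest positive and the 12 with the largest negative log2 fold change among called genes whose groups do not overlap and whose mean CPM is at least 5 in the higher group. To these come up to 4 members of each described list with the smallest p, and a fixed set of genes named whatever their values (among them TWIST1, SNAI1, SNAI2, ZEB1, ZEB2, CDH1, CDH2, VIM, FN1, MAPK3, DUSP6, SPRY4, EGR1, FOS and CDKN1A). The last part of the rule takes genes called in opposite directions in the paired Carbo vs control fit and in Carbo+COM33 vs Carbo. The 10 with the largest changes were taken in each direction. CDH1 was not tested, with 11 counts in total over the 9 libraries.

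The alternatives were DESeq2, median-of-ratios size factors, other filters on low counts, the libraries of the compared groups alone, the replicate block, limma on log2 FPKM with pseudocounts of 1 and 0.1, stricter thresholds, and each library left out in turn. Several were added only after the data had been seen: the restriction of the replicate block to the 6 control and Carbo libraries (the paired fit), offsets that remove each library's smooth trend with GC content and transcript length, the paired fit with these offsets, the paired fit without each pair, and a fit without both Carbo 3 and Carbo+COM33 3. The medians of all lists under each alternative were also written only then. The steps were tested on simulated data drawn at the libraries' own means and depths, with the dispersions of the unpaired fit of 9 libraries. For Carbo+COM33 vs Carbo, 40.3% of 67 genes changed 1.5-fold, 70.2% of 67 changed 2-fold and 90.9% of 66 changed 4-fold were called, with 9 false calls among 16450 genes. For Carbo+COM33 vs control these shares were 46.3%, 74.6% and 98.5%, with 11 false calls. For Carbo vs control in the unpaired fit of 9 libraries they were 41.8%, 70.2% and 90.9%, with 14 false calls. With simulated pair effects added, the unpaired test on the 6 libraries called 0%, 4.48% and 77.3%, and the paired test 20.9%, 68.7% and 89.4% with 9 false calls. These pair effects came on top of dispersions that already held the spread between replicates. The shares with pair effects thus do not measure power on the real libraries. A simulated trend with GC content alone gave 3757 false calls without the offsets and 0 with them. No library was left out of the comparisons.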

Results

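Gene expression was measured by RNA sequencing in SKOV3 cells, an established human ovarian cancer cell line, in 3 groups of 3 libraries: control, Carbo (carboplatin) and Carbo+COM33. Total counts ran from 13851760 to 15533668 per library over 32378 genes, of which 16450 were tested. By its title and design text, the series asks which genes, above all those of the epithelial-mesenchymal transition (EMT) and of ERK signalling, respond to carboplatin, and how expression differs when COM33 is added. Coordinates are on GRCh38. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists from camera.

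Carbo vs control asks what carboplatin changed. Genes of cell division were higher in the Carbo libraries. All 54 genes of the G2/M and mitosis list had a positive log2 fold change, with a median of 0.56 (camera adjusted p = 5.42e-26, and adjusted p = 0.771 with an estimated correlation). Of these, 0 were called over all genes and 49 rose when adjusted over the list alone. With the libraries paired by replicate number, 48 rose over all genes and 0 fell. The genes of G1/S and DNA replication had a median of 0.42 over 44 members (adjusted p = 3.44e-12, and 0.771 with an estimated correlation). Of these, 22 rose when adjusted over the list alone, and 33 rose in the paired fit. For DNA repair and damage signalling the median was 0.20 over 48 members (adjusted p = 5.70e-07, and 0.771 with an estimated correlation); 4 rose when adjusted over the list alone and 22 in the paired fit. These 3 lists were called with each of the 9 libraries left out, and after removal of the trends with GC content and length. In the paired fit ASPM, a protein of the mitotic spindle, rose from 58.4 ± 8.01 to 99.8 ± 19.5 CPM (SD, n = 3; log2 fold change 0.77, SE 0.072, adjusted p = 3.40e-06). TTK, a kinase of the spindle checkpoint, rose from 37.1 ± 1.15 to 63.0 ± 11.8 CPM (log2 fold change 0.75). MCM4, a subunit of the replicative helicase, rose by a log2 fold change of 0.61, and E2F1, a transcription factor of S-phase entry, by 0.60. BRCA2, which acts in homologous recombination, rose by 0.61, and FANCI, of the Fanconi pathway of crosslink repair, by 0.54. Each of these 6 genes was higher in Carbo in 3 of 3 pairs, and was called with each pair left out and after the GC and length correction.

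**Figure D1:**
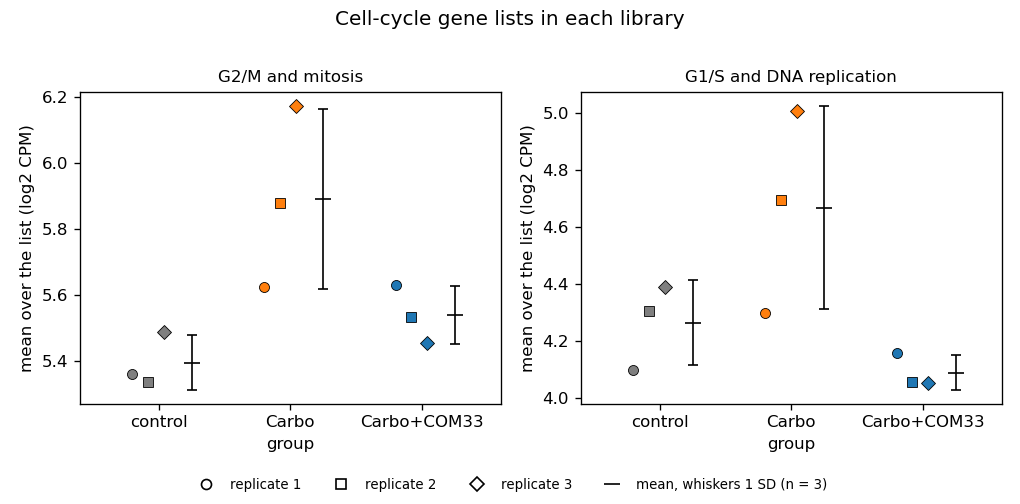
Mean log2 CPM of the G2/M and mitosis list (left) and the G1/S and DNA replication list (right) in each of the 9 libraries, with the mean and SD of each group. The mitosis list lies between 5.34 and 5.49 in control, between 5.63 and 6.17 in Carbo and between 5.45 and 5.63 in Carbo+COM33.

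Over all genes, the unpaired edgeR quasi-likelihood test of Carbo vs control called 0 genes (lowest adjusted p = 0.220). At an unadjusted p under 0.05 there were 2748 genes, 16.7% of those tested, and DESeq2 called 132. The 3 values of each group did not overlap for 3694 genes, 22.5%, where chance gives 10% on average. Genes are not independent, so such a share can lie far from 10% without an effect of treatment. Without Carbo 1, edgeR called 1034 genes. In the paired fit 3739 genes were called, 1847 up and 1892 down, with a median absolute log2 fold change of 0.29; 84 of them exceeded 1. The replicate block over all 9 libraries gave 0. Leaving out pair 1, 2 or 3 gave 4338, 1623 and 2842 calls, each with 1 residual degree of freedom. Genes of high GC content moved together: the 2275 genes with over 60% GC had a median log2 fold change of -0.24 in the paired fit (13 up, 816 down), and the 2592 genes under 40% GC a median of 0.16 (818 up, 11 down). With each library's trend with GC content and length removed, the paired fit called 1713 genes, 812 up and 901 down; 1208 of the 3739 were called in the same direction.

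Among the largest changes of the paired fit, CYP24A1, the enzyme that degrades active vitamin D (ENSG00000019186, chromosome 20, 54153449 to 54173973), rose from 42.0 ± 24.7 to 129 ± 108 CPM (SD, n = 3; log2 fold change 1.46, SE 0.136, adjusted p = 3.25e-06). CENPU, a centromere protein, rose by a log2 fold change of 0.99, BRIP1, a helicase of crosslink repair, by 0.84, KIF18A, a mitotic kinesin, by 0.84, NEK2, a centrosomal kinase, by 0.84, and TGFB2, a transforming growth factor, by 0.96. FAM111B (1.15), ANKRD1 (1.03) and FANCB (0.95) rose as well. EDF1, a transcriptional coactivator (ENSG00000107223, chromosome 9, 136862119 to 136866286), fell from 196 ± 61.4 to 90.9 ± 33.6 CPM (log2 fold change -1.12, SE 0.0513, adjusted p = 1.45e-09). S100A2, a calcium-binding protein, fell by 1.10 on the log2 scale, KCNQ1, a potassium channel, by a log2 fold change of -1.28, and NDUFA1, a subunit of respiratory complex I, by -1.12. These genes moved the same way in 3 of 3 pairs, which was required for naming by size in this fit. They were called with each pair left out and after the GC and length correction. Values of -1.94 for TBC1D3L, -1.02 for FTH1, -1.03 for SERF2 and 0.92 for FAM72A are uncertain, since these genes have close paralogs or pseudogenes.

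Of the transcription factors and markers of EMT, none was called in the unpaired Carbo vs control test, in which the count over all genes was also 0. The log2 fold change was -0.20 for TWIST1, -0.07 for SNAI1, 0.14 for SNAI2, 0.27 for ZEB1 and 0.07 for ZEB2, all of them transcription factors that drive EMT, and 0.23 for CDH2 (N-cadherin), 0.26 for VIM (vimentin) and 0.09 for FN1 (fibronectin). Adjusted p lay between 0.281 for ZEB1 and 0.950 for SNAI1. In the paired fit ZEB1 (0.26, adjusted p = 0.00258), CDH2 (0.22, adjusted p = 0.0111) and VIM (0.24, adjusted p = 0.00818) rose. ZEB1 was not called without pair 2 (adjusted p = 0.0848), nor were CDH2 and VIM without pair 2 or pair 3 (adjusted p up to 0.129 and 0.0647). After the GC and length correction in the paired fit, the log2 fold change was 0.08 for ZEB1 (adjusted p = 0.406) and 0.14 for CDH2 (adjusted p = 0.118), neither called, and 0.20 for VIM (adjusted p = 0.0243). CDH1 (E-cadherin), at 11 counts in total, was not tested. As lists, the 16 EMT transcription factors had a median of -0.07 (adjusted p = 0.839; 1 rose and 1 fell in the paired fit, and 0 in it after the correction), and the 27 mesenchymal genes a median of 0.03 (adjusted p = 0.839; mean 0.0009, while camera's direction was down; 6 rose and 5 fell in the paired fit, and 3 and 3 in it after the correction). VCAN (versican) at 0.63 and TNC (tenascin) at -0.52 moved apart in the paired fit. The 30 epithelial genes had a median of -0.002 (adjusted p = 0.727; 4 rose and 6 fell in the paired fit, CLDN7, a claudin, by -0.71, and 6 rose and 1 fell in it after the correction). In the unpaired test without Carbo 1, CD24 (0.44, adjusted p = 0.0224) was higher, and CLDN7 (-0.88, adjusted p = 0.0298) and PKP3 (-0.46, adjusted p = 0.0424) were lower. COL5A1, of the mesenchymal list, was also lower there (-0.49, adjusted p = 0.0403). The median of the 30 epithelial genes became 0.09 and their list was called upward after the GC and length correction (adjusted p = 0.0397). In the paired fit with the correction its adjusted p = 0.518 with an estimated correlation.

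ERK output did not pass the test as a list in Carbo vs control. The 31 genes of ERK transcriptional output had a median log2 fold change of 0.01 (adjusted p = 0.839; the mean of -0.009 and camera's direction have the other sign). In the paired fit 2 rose and 4 fell, and with the GC and length correction 5 rose and 2 fell. DUSP6 and SPRY4, feedback inhibitors of the pathway, had log2 fold changes of 0.04 and -0.09, and MAPK3, which encodes the kinase ERK1, one of -0.05. The immediate early gene FOS stood at 0.54. EGR1, another immediate early gene, stood at 0.46 and rose in the paired fit (0.45, adjusted p = 0.00140, and 0.0715 without pair 2). HBEGF, a ligand of the EGF receptor, also rose in the paired fit (0.52, adjusted p = 0.00608, and 0.0661 without pair 3; 0.79 in the unpaired test without Carbo 1, adjusted p = 0.0138), while LIF, a cytokine, fell (-0.28, adjusted p = 6.63e-04). The 34 MAPK cascade components had a median of 0.08 (adjusted p = 0.727; 8 rose and 8 fell in the paired fit, and 3 rose and 1 fell in it after the correction). CDKN1A, the cell-cycle inhibitor p21 and a target of p53, was at 131 ± 28.9 CPM in Carbo and 171 ± 35.0 in control (unpaired log2 fold change -0.38, adjusted p = 0.269); in the paired fit it fell by 0.39 on the log2 scale (adjusted p = 6.12e-05), and without Carbo 1 it was called in the unpaired test (log2 fold change -0.56, adjusted p = 0.0331). The 31 p53 targets had a median of -0.03 (adjusted p = 0.2403); in the paired fit 1 rose and 9 fell, among them PHLDA3 at -0.67 (1 and 5 after the correction).

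**Figure D2:**
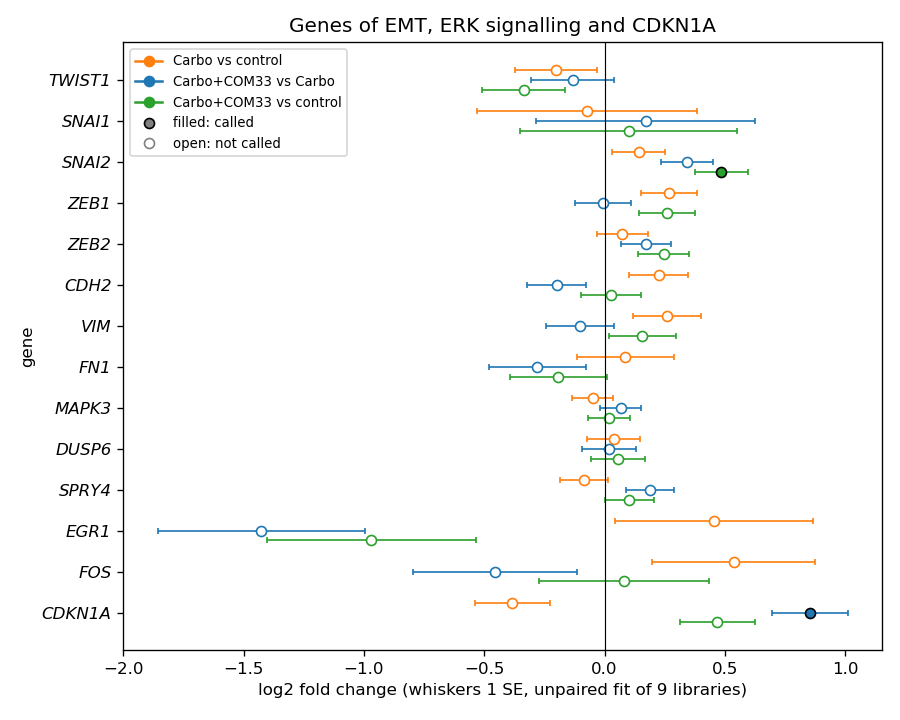
Log2 fold change (x axis; whiskers, 1 SE of the unpaired fit of 9 libraries) of fixed EMT and ERK genes and CDKN1A in the 3 comparisons; filled points were called. SNAI2 in Carbo+COM33 vs control (0.49) and CDKN1A in Carbo+COM33 vs Carbo (0.85) are the filled points.

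Ribosomal protein genes and nuclear genes of oxidative phosphorylation and glycolysis were lower in Carbo, and mitochondrially encoded genes higher. The 78 ribosomal protein genes had a median of -0.18 (adjusted p = 1.65e-08, and 0.771 with an estimated correlation). There were 0 called when adjusted over the list alone and 47 that fell and 3 that rose in the paired fit, RPL36 by -0.84; many of these genes have processed pseudogenes. The share of counts on them was 2.57% to 2.89% in control and 2.29% to 2.54% in Carbo. The 67 nuclear genes of oxidative phosphorylation had a median of -0.14 (adjusted p = 1.11e-04, and 0.771 with an estimated correlation; 1 fell when adjusted over the list alone, and 23 fell in the paired fit, COX5B by -0.56). The 37 genes of hypoxia and glycolysis had a median of -0.16 (adjusted p = 2.93e-04, and 0.771 with an estimated correlation); 17 fell in the paired fit, among them the lactate exporter SLC16A3 (-0.61) and the angiogenic factor VEGFA (-0.44). The ATF4 and unfolded protein response list stood at -0.15 (adjusted p = 0.0489, and 0.896 with an estimated correlation; 1 rose and 2 fell when adjusted over the list alone, and 3 rose and 19 fell in the paired fit, DDIT4, an inhibitor of mTORC1, by -0.91). It was not called without control 1, Carbo 2, Carbo 3 or any single Carbo+COM33 library (adjusted p up to 0.465), nor with RLE size factors, nor after the GC and length correction (adjusted p = 0.346). The 12 mitochondrially encoded genes had a median of 0.22 (adjusted p = 0.0243, and 0.818 with an estimated correlation; 9 rose and 1 fell in the paired fit); without control 1, Carbo 2 or Carbo 3 the list was not called (adjusted p up to 0.282). After the GC and length correction of the paired fit, 5 ribosomal protein genes rose and 40 fell, 2 and 17 of oxidative phosphorylation, 0 and 12 of hypoxia and glycolysis, 4 and 11 of the ATF4 list and 10 and 1 of the mitochondrially encoded genes. Many ribosomal protein genes are short, and short genes were lower in Carbo as a class: those with transcripts under 1 kb had a median of -0.09 in the paired fit (24 up, 129 down; 33 and 45 after the correction).

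The other lists were not called in Carbo vs control with all 9 libraries as counted, and no gene of theirs was called in the unpaired test. Their median log2 fold changes were -0.06 for AP-1 and immediate early genes, 0.22 for histones, -0.11 for apoptosis regulators, 0.03 for NF-kB and inflammatory cytokines, 0.02 for interferon-stimulated genes (mean -0.02), -0.12 for NRF2 antioxidant genes and 0.03 for heat shock proteins. They were 0.04 for cholesterol synthesis (fry's direction was down), 0.10 for TGF-beta targets, -0.03 for WNT targets (mean 0.02) and 0.09 for YAP and TEAD targets. Further medians were 0.04 for integrins and focal adhesion, -0.04 for platinum transport, -0.01 for metallothioneins (mean 0.008), 0.0009 for nuclear-retained long RNAs (mean -0.03) and 0.14 for senescence genes. Markers of endothelium, nerve, liver and muscle had a median of -0.45 over 6 genes, those of mesothelium and fallopian tube 0.11 over 13 (camera's direction was down), and the blood and immune markers had too few expressed genes to be tested as a list. In the paired fit 12 TGF-beta targets rose and 5 fell, 8 YAP and TEAD targets rose and 3 fell, 2 NRF2 genes rose and 11 fell, and 5 apoptosis regulators rose and 11 fell. After the GC and length correction of that fit, these counts were 11 and 2, 8 and 1, 1 and 6, and 2 and 8. With the correction of the unpaired fit, NF-kB genes (median 0.12, adjusted p = 0.0138) and AP-1 genes (0.09, adjusted p = 0.0211) were called upward and nuclear-retained long RNAs downward (-0.15, adjusted p = 0.00604). With the correction of the paired fit, TGF-beta targets (0.11, adjusted p = 0.00428), YAP and TEAD targets (0.14, adjusted p = 0.0256) and mesothelial and fallopian-tube markers (0.18, adjusted p = 0.0439) were called upward as well. The lists called in that corrected paired fit had an adjusted p of 0.518 to 0.552 with an estimated correlation. The NRF2 list was called downward without control 2 or Carbo 1 (lowest adjusted p = 0.00975), the YAP and TEAD list upward without Carbo 1 (adjusted p = 0.00247), and the markers of endothelium, nerve, liver and muscle downward without control 2 (adjusted p = 0.0169). With all 9 libraries the lowest adjusted p of any list was 0.771 with an estimated correlation. In these poly-T selected libraries the histone list had 11 tested genes and held 0.0040% to 0.0059% of counts. Its values in each comparison are therefore imprecise.

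Carbo+COM33 vs Carbo asks what adding COM33 changed in carboplatin-treated cells. SMOC1, a secreted calcium-binding protein of the matrix (ENSG00000198732, chromosome 14, 69854131 to 70032366), fell from 33.7 ± 3.82 to 4.62 ± 0.611 CPM (SD, n = 3; log2 fold change -2.86, SE 0.201, adjusted p = 4.98e-05). DMBT1, a mucin-like scavenger receptor (ENSG00000187908, chromosome 10, 122560665 to 122643736), fell from 8.91 ± 3.32 to 1.18 ± 0.492 CPM (log2 fold change -2.90, SE 0.365, adjusted p = 0.00194). CPNE7, a copine that binds phospholipids (ENSG00000178773, chromosome 16, 89575768 to 89597246), rose from 8.25 ± 2.58 to 31.6 ± 2.38 CPM (log2 fold change 1.94, SE 0.181, adjusted p = 5.02e-04). HRK, a BH3-only activator of apoptosis (ENSG00000135116, chromosome 12, 116856144 to 116881441), rose from 14.4 ± 3.96 to 46.2 ± 1.72 CPM (log2 fold change 1.68, SE 0.172, adjusted p = 5.02e-04). ASB2, a subunit of ubiquitin ligases, rose by a log2 fold change of 2.01, DYSF, which acts in repair of the plasma membrane, by 1.83, the interleukin 6 receptor gene IL6R by 1.90, and LIMCH1, a regulator of actomyosin, changed by -2.12. In each of these genes the 3 values of one group lay above the 3 of the other, which was required for naming by size. Each was called with any 1 of the 9 libraries left out. TM4SF19 (2.39) rose too; it lies in the region of TM4SF19-AS1 (1.75, not called without Carbo 2 at adjusted p = 0.0734), and the strand setting of the counting is not known, so the values of both are uncertain.

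**Figure D3:**
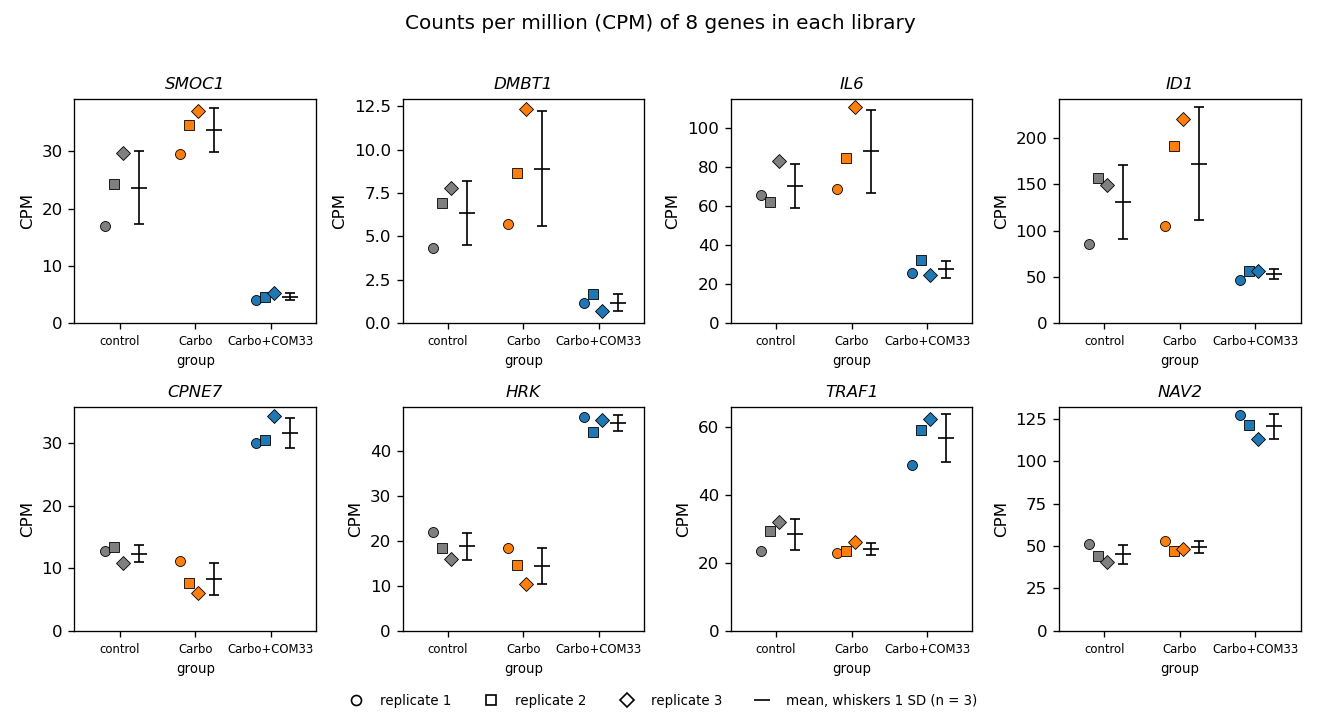
CPM (y axis) of 8 genes in each of the 9 libraries, by group, with the mean and SD of each group. SMOC1 lies at 4.05 to 5.26 CPM in the Carbo+COM33 libraries and HRK at a mean of 46.2 CPM, apart from both other groups.

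In total 816 genes were called in Carbo+COM33 vs Carbo, 400 up and 416 down, with a median absolute log2 fold change of 0.65; 199 of them exceeded 1 (74 up, 125 down). The groups did not overlap for 3892 genes, 23.7%, where chance gives 10% on average over genes that are not independent. The count changed with single libraries: it was 2721 without Carbo 1, 120 without Carbo 2, 262 without Carbo 3, 234, 239 and 488 without Carbo+COM33 1, 2 and 3, and 509 without control 2. Of the 24 genes with the largest changes, 10 were called with each of the 9 libraries left out. Others were not: CRYM, a thyroid hormone-binding protein (2.502), and SPP1 (osteopontin, 1.76) were not called without Carbo 2 or Carbo+COM33 1, KCP (2.19) not without Carbo 2 or Carbo+COM33 2. CYP24A1 (-3.07) and the matrix protein THBS1 (-2.40) were not called without Carbo 2, Carbo 3 or any single Carbo+COM33 library, with adjusted p up to 0.127. KRT81 (-3.60) and ANKRD20A19P (-2.25), called at adjusted p of 0.0196 and 0.0152 and lost in the same 5 leave-outs, have close paralogs and are uncertain.

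Cell-cycle genes fell when COM33 was added. The G1/S and DNA replication list had a median log2 fold change of -0.55 (camera adjusted p = 3.90e-13, and adjusted p = 0.448 with an estimated correlation); 14 of 44 members fell over all genes, and 33 when adjusted over the list alone. E2F1 fell from 38.5 ± 12.7 to 17.6 ± 2.30 CPM (log2 fold change -1.13, SE 0.210, adjusted p = 0.0106), E2F2, a related factor, by -1.998 (adjusted p = 0.00776) and the helicase subunit MCM7 by -0.91 (adjusted p = 0.0118). These 3 were not called without Carbo 2, Carbo+COM33 1 or Carbo+COM33 2 (adjusted p up to 0.0683). The G2/M and mitosis list had a median of -0.36 (adjusted p = 1.96e-10, and 0.492 with an estimated correlation); 3 of 54 members fell, and 27 when adjusted over the list alone. KIF20A, a kinesin of cytokinesis, fell by -1.01 (adjusted p = 0.0144), but was not called without Carbo 2, Carbo+COM33 2 or Carbo+COM33 3 (adjusted p up to 0.0643). The mean log2 CPM of the mitosis list was 5.63 in Carbo 1, 5.88 in Carbo 2 and 6.17 in Carbo 3, against 5.63, 5.53 and 5.45 in Carbo+COM33 1 to 3, so its fall was carried by Carbo 2 and 3. For the G1/S list it was 4.30, 4.70 and 5.01 in Carbo, and 4.16, 4.06 and 4.05 in Carbo+COM33. DNA repair genes had a median of -0.21 (adjusted p = 1.21e-04, and 0.448 with an estimated correlation); 1 of 48 fell, and 18 fell and 1 rose when adjusted over the list alone.

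TGF-beta and YAP targets fell as well. The TGF-beta target list had a median of -0.31 (adjusted p = 8.66e-04, and 0.492 with an estimated correlation); 7 of 34 fell and 1 rose, and 12 fell and 2 rose when adjusted over the list alone. The list's mean log2 CPM was 5.66 in Carbo 1, 6.20 in Carbo 2 and 6.25 in Carbo 3, against 5.35, 5.63 and 5.59 in Carbo+COM33 1 to 3, so Carbo 1 lay close to the Carbo+COM33 libraries. Control 1 was low as well, at 5.60 against 6.09 and 6.11 in control 2 and 3. By replicate number, each Carbo library was above the Carbo+COM33 library. ID1, an inhibitor of helix-loop-helix factors and a target of BMP signalling (ENSG00000125968, chromosome 20, 31605283 to 31606515), fell from 173 ± 60.7 to 52.7 ± 5.48 CPM (SD, n = 3; log2 fold change -1.71, SE 0.258, adjusted p = 0.00440), and INHBA, which encodes a subunit of activin, by -0.92. The inhibitory SMAD6 (-1.71) and ID3 (-1.62) fell, but were not called without Carbo 2 or Carbo+COM33 1 (adjusted p up to 0.0548). The YAP and TEAD target list had a median of -0.35 (adjusted p = 1.21e-04, and 0.448 with an estimated correlation); 8 of 25 fell, and 11 when adjusted over the list alone, among them IGFBP3, a binding protein of insulin-like growth factors (-0.80), and F3, tissue factor (-0.89). This list's mean was 6.29 in Carbo 1, 6.71 in Carbo 2 and 6.82 in Carbo 3, and 6.10 to 6.23 in Carbo+COM33. Of the WNT targets, which were not called as a list (median -0.23, adjusted p = 0.191), DKK1, a secreted inhibitor of WNT signalling, fell by -1.39 (adjusted p = 0.00473). ID1, INHBA, IGFBP3, F3 and DKK1 were called with any 1 library left out.

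Genes of NF-kB signalling moved in both directions. Of 28 members of the list, 5 rose and 6 fell (9 and 7 when adjusted over the list alone), and the list was not called (median 0.19, adjusted p = 0.0740). Without Carbo 3 it was called upward (adjusted p = 0.0220), while with all 9 libraries its adjusted p = 0.448 with an estimated correlation. TNFAIP3, an inhibitor of NF-kB, rose from 143 ± 3.78 to 236 ± 12.01 CPM (log2 fold change 0.72, SE 0.075, adjusted p = 5.02e-04). TRAF1, an adaptor of TNF receptors, rose from 24.2 ± 1.74 to 56.8 ± 7.14 CPM (1.23), and CSF1, a growth factor of macrophages, from 198 ± 20.7 to 332 ± 19.95 CPM (0.75). The cytokine IL6 (ENSG00000136244, chromosome 7, 22725884 to 22732002) fell from 87.8 ± 21.04 to 27.5 ± 4.29 CPM (log2 fold change -1.67, SE 0.173, adjusted p = 5.02e-04). These 4 genes were called with any 1 library left out.

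Regulators of apoptosis and p53 targets were higher. The apoptosis list had a median of 0.12 (adjusted p = 0.0189, and 0.448 with an estimated correlation), and 3 of 35 members rose, HRK the most; 7 rose when adjusted over the list alone. The p53 target list had a median of 0.21 (adjusted p = 0.0338, and 0.448 with an estimated correlation); 5 of 31 rose and 1 fell, and 5 rose and 2 fell when adjusted over the list alone. Neither list was called without Carbo 1 or Carbo+COM33 3 (adjusted p up to 0.0876 and 0.141). CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339) rose from 131 ± 28.9 to 237 ± 18.3 CPM (log2 fold change 0.85, SE 0.158, adjusted p = 0.0104), but was not called without Carbo 2 (adjusted p = 0.0725). Interferon-stimulated genes had a median of 0.08 (adjusted p = 0.0381, and 0.448 with an estimated correlation); 6 of 40 rose, and 9 rose and 1 fell when adjusted over the list alone, among them the transcription factor IRF1 (0.98; not called without Carbo 2, adjusted p = 0.0602). That list was not called without control 1, Carbo 1, Carbo 2 or Carbo+COM33 2 (adjusted p up to 0.2502).

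Among EMT genes, 1 transcription factor was called in Carbo+COM33 vs Carbo: FOXC1 rose (0.47, adjusted p = 0.0425), and was not called without any 1 of 7 libraries, control 1 and Carbo 1 excepted (adjusted p up to 0.175). The log2 fold change was -0.13 for TWIST1, 0.17 for SNAI1, 0.34 for SNAI2 (adjusted p = 0.0901), -0.008 for ZEB1, 0.17 for ZEB2, -0.20 for CDH2, -0.10 for VIM and -0.28 for FN1. The EMT transcription factor list had a median of 0.07 (adjusted p = 0.280) and the mesenchymal list one of -0.20 with 0 of 27 members called, also when adjusted over the list alone (adjusted p = 0.232). That depended on Carbo 1, in which the mesenchymal list's mean log2 CPM was 5.23, against 5.79 and 5.75 in Carbo 2 and 3 and 5.20 to 5.37 in Carbo+COM33. Carbo 1 did not stand alone, since control 1 was low as well, at 5.18 against 5.81 and 5.8 in control 2 and 3. Without Carbo 1, VCAN (-1.71, adjusted p = 2.65e-04), the collagens COL1A1 (-1.99, adjusted p = 0.00349) and COL5A2 (-0.81, adjusted p = 0.00528) and TGFBI, a matrix protein (-1.36, adjusted p = 0.00375), were called as lower. Without control 1, VCAN, COL1A1 and TGFBI were (adjusted p of 0.0260, 0.0334 and 0.0372). Epithelial genes had a median of -0.14 (adjusted p = 0.0367, and 0.448 with an estimated correlation); 3 of 30 fell, and 7 fell and 1 rose when adjusted over the list alone. KRT7, a keratin of simple epithelia, fell by -1.21 (adjusted p = 0.00893) and JUP, plakoglobin of cell junctions, by -0.72 (adjusted p = 0.0104). Both were not called without Carbo 2 or Carbo+COM33 1 (adjusted p up to 0.0750). EHF, an epithelial transcription factor, was called as lower without control 1 or Carbo 1 (adjusted p of 0.0348 and 5.63e-04). The epithelial list was not called without Carbo 1, Carbo 2, Carbo+COM33 1 or Carbo+COM33 2 (adjusted p up to 0.1196).

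ERK output showed 3 genes up and 3 down of 31 in Carbo+COM33 vs Carbo, and 4 up and 5 down when adjusted over the list alone. The list was not called (median 0.02, mean -0.04, camera's direction up, adjusted p = 0.613). DUSP5, a nuclear phosphatase of ERK, rose from 112 ± 3.42 to 162 ± 10.5 CPM (SD, n = 3; log2 fold change 0.53, SE 0.075, adjusted p = 0.00335), while DUSP4, of the same family, fell from 123 ± 1.02 to 91.0 ± 0.681 CPM (log2 fold change -0.44, SE 0.0679, adjusted p = 0.00468). Both were called with any 1 library left out. CCND1, cyclin D1 (0.68), and the transcription factor KLF6 (0.58) rose, but were not called without Carbo 2 (adjusted p = 0.0598 and 0.0602). DUSP6 (0.02), SPRY4 (0.19), MAPK3 (0.07), FOS (-0.46) and EGR1 (-1.43, adjusted p = 0.0765) were not called. Without control 1 or Carbo 1, EGR1 was called as lower (adjusted p = 0.0272 and 0.00165). Among the MAPK cascade components (34 genes, median 0.03, mean -0.06, camera's direction down, adjusted p = 0.917), 2 fell; ERBB2, a receptor tyrosine kinase, did so from 2415 ± 155 to 1630 ± 159 CPM (log2 fold change -0.57, adjusted p = 0.00508) with any 1 library left out.

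Further lists were called at the preset correlation, and none with an estimated one. They are ATF4 and the unfolded protein response (median 0.21, adjusted p = 0.00592, and 0.562 with an estimated correlation; 3 up, 1 down), oxidative phosphorylation (0.13, adjusted p = 0.00215, and 0.492 with an estimated correlation), NRF2 antioxidant genes (-0.11, adjusted p = 0.0338, and 0.492 with an estimated correlation; 3 down) and markers of endothelium, nerve, liver and muscle (0.41 over 6 genes, adjusted p = 0.0338, and 0.448 with an estimated correlation). Of the oxidative phosphorylation genes 1 was called, NDUFV2, which fell by -1.02, against the list. The NRF2 list was not called without Carbo 1 or Carbo+COM33 2 (adjusted p up to 0.382). Oxidative phosphorylation was not called without Carbo+COM33 3 (adjusted p = 0.0955) nor after the GC and length correction (adjusted p = 0.138), and the markers of other tissues not without Carbo 2, Carbo+COM33 1 or Carbo+COM33 3 (adjusted p up to 0.0864). Of the latter MBP, a myelin gene also read in other cells, rose by 0.45 (not called without Carbo 2, Carbo 3 or Carbo+COM33 1, adjusted p up to 0.0804). AKR1C1, an aldo-keto reductase of the NRF2 list, fell by -0.66, CA12, a carbonic anhydrase, by -0.93, and ANGPTL4, an inhibitor of lipoprotein lipase, by -1.41. The small heat shock protein gene HSPB8 rose by 1.04. These 4 were called with any 1 library left out.

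The lists not called in Carbo+COM33 vs Carbo, with members up and down, were AP-1 genes (median 0.02, mean -0.01; 4 and 3), histones (-0.22; 0 and 2), heat shock proteins (-0.03, camera's direction up; 1 and 0) and cholesterol synthesis (-0.03, camera's direction up; 2 and 1). Hypoxia and glycolysis (-0.10; 1 and 4), WNT targets (1 and 3), integrins and focal adhesion (-0.09; 4 and 4), platinum transport (-0.06; 3 and 0) and metallothioneins (0.07; 0 and 0) follow. Ribosomal proteins (0.10; 0 and 2), mitochondrially encoded genes (-0.12; 0 and 0), nuclear-retained long RNAs (-0.02; 0 and 0), senescence genes (-0.12; 3 and 7) and mesothelial and fallopian-tube markers (0.02; 1 and 0) complete them. Some of these were called with 1 library left out: histones without Carbo+COM33 1 (adjusted p = 0.0488), hypoxia and glycolysis without Carbo 3 (adjusted p = 0.0430), and ribosomal proteins and mitochondrially encoded genes without Carbo+COM33 2 (adjusted p = 0.0208 and 0.0436). The histone list rests on 11 tested genes with few counts. With all 9 libraries the lowest adjusted p of any list was 0.448 with an estimated correlation.

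Carbo+COM33 vs control compares the combined treatment with untreated cells. NAV2, a cytoskeletal protein first known from nerve cells (ENSG00000166833, chromosome 11, 19350724 to 20121598), rose from 45.3 ± 5.55 to 121 ± 7.27 CPM (SD, n = 3; log2 fold change 1.41, SE 0.1003, adjusted p = 5.84e-05). CSF2, the cytokine GM-CSF (ENSG00000164400, chromosome 5, 132073790 to 132076170), rose from 2.81 ± 1.11 to 10.8 ± 1.01 CPM (log2 fold change 1.94, SE 0.237, adjusted p = 0.00186). SMOC1 fell from 23.7 ± 6.41 to 4.62 ± 0.611 CPM (log2 fold change -2.35, SE 0.202, adjusted p = 2.78e-04), and EBP, an isomerase of cholesterol synthesis, from 59.0 ± 3.81 to 31.5 ± 0.893 CPM (log2 fold change -0.90, SE 0.0842, adjusted p = 3.64e-04). KRT17, a keratin, fell by -1.75, the neurotrophin gene BDNF by -1.66, MXRA8, a membrane protein of the matrix, by -1.65, ANGPTL4 by -1.86 and DMBT1 by -2.42. NDRG4, of a family of stress-responsive proteins, rose by 1.48. In each the 3 values of the groups did not overlap, which was required of genes named by size. Each was called with any 1 library left out.

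In this comparison 1035 genes were called, 527 up and 508 down, with a median absolute log2 fold change of 0.55; 161 of them exceeded 1 (62 up, 99 down). Non-overlapping groups were found for 4723 genes, 28.7%, where chance gives 10% on average over genes that are not independent. The count was 114 without control 2, 203 without control 3, 1809 without Carbo 1, 631 without Carbo 2, and 153, 177 and 2208 without Carbo+COM33 1, 2 and 3. Of the 24 largest changes, 14 were called with each of the 9 libraries left out. Genes with over 60% GC had a median log2 fold change of -0.21 (16 up, 181 down) and those under 40% GC one of 0.14 (164 up, 12 down), while in Carbo+COM33 vs Carbo these medians were 0.03 and -0.04.

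**Figure D4:**
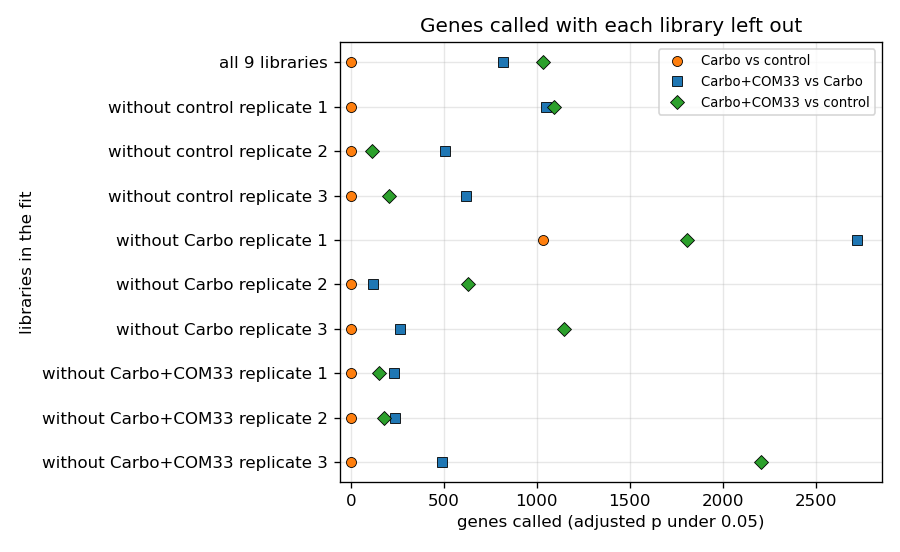
Number of genes called (x axis) in each comparison with all 9 libraries and with each library left out (y axis). Counts for Carbo+COM33 vs Carbo run from 120 to 2721, for Carbo+COM33 vs control from 114 to 2208, and for Carbo vs control from 0 to 1034.

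NF-kB genes again moved in both directions: 7 of 28 rose and 4 fell in Carbo+COM33 vs control (11 and 4 when adjusted over the list alone), and the list was not called (median 0.17, adjusted p = 0.0522). Without control 2 or 3, Carbo 1, or Carbo+COM33 1 or 2 the adjusted p was under 0.05, the lowest at 0.0268; after the GC and length correction it was 0.0226. With all 9 libraries the list had an adjusted p = 0.809 with an estimated correlation, and 0.0648 by fry. TNFAIP3 (0.84) and CSF1 (0.76) rose and IL6 (-1.35) fell, each with any 1 library left out. Hypoxia and glycolysis genes had a median of -0.25 (adjusted p = 1.34e-04, and 0.809 with an estimated correlation); 7 of 37 fell, and 14 fell and 1 rose when adjusted over the list alone, ANGPTL4 and CA12 (-0.77) among them. NRF2 antioxidant genes had a median of -0.21 (adjusted p = 0.00144, and 0.809 with an estimated correlation); 7 of 29 fell and 1 rose (12 and 1 when adjusted over the list alone), including the aldo-keto reductases AKR1C1 (-0.72) and AKR1C3 (-0.64) and the quinone reductase NQO1 (-0.49). Both lists were called with each library left out and after the GC and length correction. HRK (1.30) rose in the apoptosis list, of which 4 members of 35 rose (median 0.03, adjusted p = 0.497), and HSPB8 (1.05) among the heat shock proteins (median 0.01, 1 of 23 up).

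Of the EMT genes, SNAI2, a zinc finger repressor, rose from 170 ± 12.1 to 238 ± 20.97 CPM (SD, n = 3; log2 fold change 0.49, SE 0.1098, adjusted p = 0.0249) and CD44, a hyaluronan receptor, by 0.39 (adjusted p = 0.0245). Neither was called without control 2, control 3, Carbo+COM33 1 or Carbo+COM33 2 (adjusted p up to 0.124). TWIST1 (-0.34), SNAI1 (0.10), ZEB1 (0.26), ZEB2 (0.25), CDH2 (0.03), VIM (0.16) and FN1 (-0.19) were not called. Without Carbo+COM33 3, TWIST1 (-0.54, adjusted p = 0.0466), ZEB1 (0.37, adjusted p = 0.0368) and ZEB2 (0.35, adjusted p = 0.0234) were called. The EMT transcription factors (median 0.03, mean -0.005, adjusted p = 0.555; 1 of 16 up) and the mesenchymal genes (median -0.26, adjusted p = 0.194; 1 of 27 up) were not called as lists. Of the mesenchymal genes, COL1A1 and TGFBI were called as lower without control 1 (adjusted p of 0.01995 and 0.0254) or Carbo 1 (adjusted p of 0.0159 and 0.0259). S100A4, a calcium-binding protein, was lower without Carbo 1 or Carbo+COM33 3 (adjusted p of 0.0463 and 0.0168). FOXC1 was higher without control 1, Carbo 1 or Carbo 3 (adjusted p of 0.0309, 0.0250 and 0.0468). Without control 1 the mesenchymal list was called downward (adjusted p = 0.00767); with all 9 libraries its adjusted p = 0.933 with an estimated correlation. Epithelial genes had a median of -0.22 (adjusted p = 0.0132, and 0.809 with an estimated correlation); 4 of 30 fell, and 5 when adjusted over the list alone. The list was called with each library left out, but not after the GC and length correction (adjusted p = 0.736). KRT7 fell by -1.18, but not without control 2, control 3 or Carbo+COM33 1 (adjusted p up to 0.0774).

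ERK output had 4 genes up and 2 down of 31 in Carbo+COM33 vs control (4 and 3 when adjusted over the list alone) and was not called as a list (median 0.03, mean -0.05, adjusted p = 0.858). DUSP4 fell (-0.43, adjusted p = 0.00484) with any 1 library left out. CCND1 (0.73), KLF6 (0.63) and DUSP5 (0.45) rose, but were not called without control 2 (adjusted p = 0.0515, 0.0506 and 0.0561). Of the MAPK components (median 0.01, mean -0.04, adjusted p = 0.845) 2 rose and 2 fell, SHC1, an adaptor between receptors and RAS, by -0.62. MAPK3 (0.02), DUSP6 (0.06), SPRY4 (0.10), EGR1 (-0.97), FOS (0.08) and CDKN1A (0.47, adjusted p = 0.0904) were not called. CDKN1A was called without control 1 or Carbo 1 (adjusted p = 0.0250 and 0.0244), and EGR1 without control 1 (adjusted p = 0.0499).

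TGF-beta targets (median -0.36, adjusted p = 0.00457, and 0.867 with an estimated correlation; 1 up and 5 down of 34, 1 and 12 when adjusted over the list alone) and YAP and TEAD targets (-0.19, adjusted p = 0.0114, and 0.867 with an estimated correlation; 1 up and 5 down of 25, 1 and 9 when adjusted over the list alone) were lower. G2/M and mitosis genes were higher (median 0.18, adjusted p = 0.00457, and 0.933 with an estimated correlation; 1 of 54 up, KIF20B, and 0 when adjusted over the list alone). Ribosomal proteins were lower (-0.10, adjusted p = 0.00457, and 0.867 with an estimated correlation; 7 of 78 down, and 9 down and 1 up when adjusted over the list alone). After the GC and length correction the first 3 of these 4 lists were not called (adjusted p of 0.0925, 0.160 and 0.370). For TGF-beta targets the mean log2 CPM was 5.60 in control 1, within the Carbo+COM33 range of 5.35 to 5.63. It was 6.09 and 6.11 in control 2 and 3, so these carried most of the fall. By replicate number, each control was above the Carbo+COM33 library (5.349, 5.628 and 5.595 in Carbo+COM33 1 to 3). YAP and TEAD targets were not called without control 3 (adjusted p = 0.0508), nor ribosomal proteins without control 1 or Carbo+COM33 2 (adjusted p up to 0.215). Not called, with members up and down, were AP-1 genes (0.08, mean -0.01; 3 and 2), p53 targets (0.05; 1 and 0), DNA repair (-0.02, mean 0.007; 0 and 0), G1/S (-0.12; 1 and 1), histones (-0.13; 0 and 1), interferon-stimulated genes (0.11; 6 and 2), ATF4 (0.05; 0 and 0) and cholesterol synthesis (0.04, mean -0.01; 4 and 1). The same holds for WNT targets (-0.23; 2 and 3), integrins (-0.03; 3 and 4), platinum transport (-0.01; 0 and 1), metallothioneins (0.07; 1 and 0), mitochondrially encoded genes (0.10; 0 and 0), oxidative phosphorylation (-0.04; 0 and 1), nuclear-retained long RNAs (-0.04; 0 and 0), senescence genes (0.05, mean -0.19; 1 and 3), markers of endothelium, nerve, liver and muscle (0.02, mean -0.01; 1 and 0) and mesothelial and fallopian-tube markers (0.04; 1 and 1). The G1/S list was called downward without control 1, Carbo 1 or Carbo+COM33 1 (lowest adjusted p = 0.0180), and interferon-stimulated genes upward without Carbo+COM33 1 (adjusted p = 0.0433). With all 9 libraries no list had an adjusted p under 0.809 with an estimated correlation.

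The title of the series names a reversal by COM33, which asks for genes that carboplatin moved and COM33 moved back. With the unpaired test 0 genes were called in opposite directions in Carbo vs control and Carbo+COM33 vs Carbo, since the first had 0 calls at adjusted p under 0.05 and 2748 at unadjusted p under 0.05; DESeq2 gave 27, and the unpaired test without Carbo 1 gave 622. With the paired calls of Carbo vs control there were 282, 154 raised then lowered, where independent lists would share 46.7, and 128 lowered then raised, where they would share 46.0; 11 were raised and 20 lowered in both, against 44.9 and 47.9. With the GC and length correction in both fits there were 179 and 117 in opposite directions, against 31.1 and 33.7, and 9 and 12 in the same direction, against 30.4 and 34.5. Both comparisons use the Carbo libraries, so part of the excess may come from the shared libraries. For the counts that use the paired calls, no simulation without change was run; for the unpaired test, which gave 0, it gave 0.04 genes on average. Across all genes the covariance of the fold changes of Carbo vs control and Carbo+COM33 vs Carbo was -0.0550, against -0.0304 in simulated data with no change and no pairing. Their correlation was -0.437, against -0.496 in the simulated data, and 64.0% of genes went in opposite directions, against 66.5%. The Carbo libraries were also divided so that none served both comparisons. With Carbo 1, 2 or 3 set against its same-numbered control, and the other 2 used in Carbo+COM33 vs Carbo, the covariance on log2 CPM was -0.0213, -0.0326 and -0.0187. With the roles exchanged it was -5.31e-06, -0.0267 and -0.0459, and with the single library set against all 3 controls 0.0341, -0.0436 and -0.0363. In the last of these ways the controls numbered like the other 2 Carbo libraries enter the first comparison. Their shared deviations can push the covariance upward. These ways overlap and give no p-value.

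Among genes raised in the paired Carbo vs control fit and lowered by adding COM33 was PDK4, a kinase that inhibits pyruvate dehydrogenase, at log2 fold changes of 0.82 and -1.64 (3.01 ± 1.20 CPM in Carbo+COM33 and 9.37 ± 0.968 in Carbo, n = 3). It was called with each pair left out of the paired fit, and with any 1 library left out of Carbo+COM33 vs Carbo. CYP24A1 (1.46 and -3.07), THBS1 (0.72 and -2.40) and the guidance molecule SEMA3A (0.75 and -2.09) were further members. Among genes lowered and then raised, CPNE7 stood at -0.60 and 1.94, UPP1, which cleaves uridine, at -0.61 and 1.18, and HMGA1, a chromatin protein, at -0.53 and 0.86. For CYP24A1, THBS1, SEMA3A, UPP1 and HMGA1 the second change was not called without Carbo 2, Carbo 3 or any single Carbo+COM33 library (adjusted p up to 0.138). The fall of CPNE7 in Carbo was not called without pair 2 (adjusted p = 0.0841) nor after the GC and length correction (adjusted p = 0.0928). Between Carbo+COM33 vs Carbo and Carbo+COM33 vs control, which share the Carbo+COM33 libraries, 232 genes rose in both and 201 fell in both, where independent lists would share 12.8 and 12.9; 0 were called in opposite directions, and simulated data gave 0.04 shared genes.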

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

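Chosen only after the results were seen were the GC and length correction, the paired 6-library fits with and without it and without each pair, the fit without both Carbo 3 and Carbo+COM33 3, and the list medians under each alternative. Where no cause is named below, the cause was not tested.

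For genes called in Carbo vs control (0 with edgeR and all 9 libraries; 2748 at unadjusted p under 0.05), DESeq2 gave 132, all genes with a count 928, the paired 6-library block 3739, that block with the GC and length correction 1713, and that block without pair 1, 2 or 3 gave 4338, 1623 and 2842. With 1 library left out the range was 0 to 1034, and 0 in all but the fit without Carbo 1; RLE size factors, the filter at 1 CPM, the 2 groups alone, the replicate block over all 9 libraries, both FPKM tests, the stricter thresholds, the GC and length correction of the unpaired fit and the fit without both libraries gave 0 as well. For Carbo+COM33 vs Carbo (816), DESeq2 gave 1356, sharing 796 of the 816, all genes with a count 1876, the replicate block over 9 libraries 1554, log2(FPKM + 1) 447, log2(FPKM + 0.1) 446, adjusted p under 0.01 192, an absolute log2 fold change over 1 199, the GC and length correction 1246, and the fit without both Carbo 3 and Carbo+COM33 3 286. With 1 library left out the range was 120 to 2721; all 120 genes called without Carbo 2 were among the 816. RLE size factors (803), the filter at 1 CPM (816) and the 2 groups alone (618) stayed within 1.5 times. For Carbo+COM33 vs control (1035), DESeq2 gave 1563, sharing 1004 of the 1035, all genes with a count 1934, the replicate block over 9 libraries 1625, log2(FPKM + 1) 656, log2(FPKM + 0.1) 652, adjusted p under 0.01 159, an absolute log2 fold change over 1 161, and the fit without both libraries 2623. With 1 library left out the range was 114 to 2208. RLE size factors (1067), the filter at 1 CPM (1046), the 2 groups alone (1462) and the GC and length correction (912, sharing 678) stayed within 1.5 times. The stricter thresholds lower the counts by construction. Across genes, the Carbo+COM33 libraries showed no steady pairing with the others by replicate number. Same-numbered deviations correlated at -0.0150, 0.138 and -0.388 with Carbo and at 0.0851, 0.101 and -0.420 with control. The block values of these comparisons are therefore given here alone. Pairing is not excluded, since the block raised both counts. The mean log2 CPM of TGF-beta targets was lowest in replicate 1 of each group (5.60 in control, 5.66 in Carbo, 5.35 in Carbo+COM33). For G1/S and DNA replication it was lowest in control 1 and Carbo 1 but highest in Carbo+COM33 1.

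For genes called in opposite directions in Carbo vs control and Carbo+COM33 vs Carbo (0), DESeq2 gave 27, all genes with a count 380, the paired block 282 and the paired block with the GC and length correction 296. With 1 library left out the range was 0 to 622. For lists called (8, 13 and 7 in Carbo vs control, Carbo+COM33 vs Carbo and Carbo+COM33 vs control), an estimated correlation gave 0, 0 and 0 and fry gave 0, 0 and 0, with lowest fry adjusted p of 0.252, 0.0831 and 0.0648. In the paired Carbo vs control fit fry called 1 list (adjusted p = 0.0406), and 0 after the GC and length correction (lowest fry adjusted p = 0.0574). An estimated correlation gave 0 in both. In Carbo vs control the paired block with the GC and length correction gave 14 lists; in Carbo+COM33 vs control the correction gave 4. With 1 library left out the ranges were 6 to 10, 8 to 15 and 7 to 10. After the GC and length correction, the Carbo vs control medians changed sign, with a call, for epithelial genes (0.0891, adjusted p = 0.0397), AP-1 and immediate early genes (0.0880, adjusted p = 0.0211) and nuclear-retained long RNAs (-0.153, adjusted p = 0.00604). Medians near 0 also changed sign without a call: ERK transcriptional output (-0.0007), interferon-stimulated genes (-0.02), WNT targets (0.03) and platinum transport (0.03) in Carbo vs control, AP-1 genes (-0.0005) and mesothelial markers (-0.02) in Carbo+COM33 vs Carbo, and integrins (0.003), platinum transport (0.01) and senescence genes (-0.005) in Carbo+COM33 vs control. Of the 113 named genes called in Carbo+COM33 vs Carbo, 1 (OCIAD2) lost its call with the correction, and of the 93 in Carbo+COM33 vs control 12 did. Library totals of 13851760 to 15533668 counts limit what can be read of genes with few counts, such as CDH1 with 11.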

Other observations

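The test of the GC and length trends, the tests of the covariance (by rotation, with the pairs kept together and with no Carbo library in both comparisons) and the splits of Carbo vs control were chosen only after the results were seen.

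Among the 10 splits of 6 libraries into 3 and 3, the real split of Carbo+COM33 vs Carbo called 618 genes and the highest other split 0, so that 1 split gave as many. For Carbo+COM33 vs control the real split called 1462 and the highest other 0, again 1 split with as many. For Carbo vs control the real split called 0 in the unpaired edgeR test (2748 genes at unadjusted p under 0.05 in the fit of 9 libraries, and 132 called by DESeq2). The highest other split also gave 0, so all 10 splits gave as many. With 0 calls in the real split this outcome was fixed beforehand, so it decides nothing. Of the 4 swaps within the 3 pairs, the real one called 3739 genes in the paired test and the highest other 0, so that 1 gave as many. The splits are too few for a share under 0.05 in each case.

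Genes with a high GC content were lower in Carbo than in control and those with a low GC content higher, and the calls of the paired Carbo vs control fit may follow this trend in part. With each library's trend with GC content and transcript length removed, 32.3% of the 3739 paired calls were called in the same direction, which argues against the trend as the whole cause. For the rest the trend stays open: over the 3739 genes the median absolute log2 fold change went from 0.29 to 0.16 and the median SE from 0.0654 to 0.0639, so calls ended mostly because the changes became smaller, and 245 of them changed sign. A trend of this kind could come from library preparation as well as from the treatment, and no biological explanation of it was tested.

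The genes of mitosis were higher in Carbo than in control. Against a GC or length trend as the whole cause stands their median of 0.42 in the paired fit after the correction, with 49 of 54 called as higher. Against a single pair as the cause stands that the list's mean was over 0.1 higher in 3 of 3 pairs, by 0.265, 0.542 and 0.682 on the log2 scale. It stays open whether carboplatin held cells in these phases, since neither phases nor cell numbers were measured, and the list lost its call with an estimated correlation; that the treatment raised these genes remains a hypothesis.

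Fold changes in Carbo vs control and Carbo+COM33 vs Carbo went in opposite directions for 64.0% of genes, against 66.5% in simulated data without any change and without pairing. Both comparisons use the Carbo libraries, whose noise alone pushes these fold changes apart. The covariance of the fold changes on log2 CPM was -0.0482, within the central 95% of rotations of the residuals (-0.0559 to -0.00927, mean -0.0275), and 71 of 1000 rotations were as low. These rotations treat the libraries as unpaired, whereas control and Carbo deviate alike by replicate number. The noise was also taken along the same direction in all groups, so that pairs stay together. The covariance then lay between -0.0307 and -0.0194, closer to 0 than the observed value. This also pairs the Carbo+COM33 libraries by number, which their correlations across genes did not show. The range is one over directions and not a distribution without change. With no Carbo library in both comparisons the mean covariance over 9 overlapping ways to divide them was -0.0212. The values ran from -0.0459 to 0.0341, with 1 of them positive. That value came from the ways with all controls in the first comparison (mean -0.01525, SD 0.0429). There the controls numbered like the other Carbo libraries can push the covariance upward. With same-numbered controls only, the mean was -0.0242 in both arrangements (SD 0.00741 and 0.0231). This test was labelled by a rule written after its values had been seen. With 3 replicates neither test gives a distribution, so noise of the shared Carbo libraries may account for the opposite directions in part or whole, and a reversal by COM33 cannot be told apart from it.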
